A study of Homo sapiens with 16 samples.

How the data were processed

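Polyadenylated RNA of H1 human embryonic stem cells with OCT4 and SOX2 reporters was profiled by short-read sequencing in 11 libraries of 3 groups and in 5 overexpression libraries. Cells directed to ectoderm were sorted on the ratio of the reporters into pre (n = 4) and post (n = 4), about 250000 cells each. The outgroup (n = 3) was taken after mesendoderm induction, directly after dissociation and without a sort. Every library was used, and every column of both tables was read.

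The deposited unit of both tables is a signal: abundance per Ensembl gene on the TPM scale, rescaled between libraries before deposit. Column sums differ between libraries, and the values are not whole numbers. The submitters' processing notes name kallisto 0.45.1 for pseudo-alignment, sleuth 0.30.0 and the hg38 assembly for both tables. For the table of the 3 groups the submitters' processing notes also name DESeq2 1.24.0 and R 3.6.1, used by the authors in a role that is not stated. The annotation release, the summing of transcripts to genes and the scaling step are not given in the sources used here. The design had foreseen TPM or counts; the files held this other unit, and the branch for normalized values was used. Read counts are not in the files, so the number of reads per library and its counting precision are unknown, and the spread between replicates is the precision given. Relative depth was estimated from the commonest ratio of low values between libraries in genes with 1 transcript.

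The table of the 3 groups has 63723 rows, of which 57551 are in GENCODE release 29, the annotation used here for symbols and hg38 coordinates. A symbol was matched for 42764 rows. The overexpression table has 40180 rows, 35468 of them in that annotation and 30176 with a symbol, and the tables share 40093 rows. They were scaled separately, so values were compared within a table only. Over the 3 groups, 1758 rows hold the same values as another row, which marks reads shared between copies; 44, 230 and 265 of the called genes had such a copy in post against pre, outgroup against pre and outgroup against post. Y-linked genes and XIST were left out of the named genes, and some genes that the rule names are not reported here.

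Genes with a value of at least 1 in at least 3 of the 11 libraries were tested with limma 3.58.1 (trend) in R 4.3.3 on log2(value + 1). All 11 libraries were in 1 fit without a block, from which the 3 comparisons were drawn. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over lists of at least 5 tested members. Of 25 lists with 528 members, all matched to rows, 24 had enough tested members, and the HOX list was used in the overexpression libraries alone. POU5F1 and SOX2 were left out of the lists because their reporters set the gate. The overexpression libraries were compared without a test over 19126 genes, with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. Each list median was set against 10000 random lists matched on size and on 20 bins of expression. Figures were drawn with matplotlib 3.10.9.

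Replicate numbers pair pre and post libraries through shared experiments. Deviations of log2 values from the group mean correlated between same-numbered pre and post libraries at 0.35, 0.37, 0.46 and 0.26. Differently numbered libraries of the same period correlated about as much. These values were 0.43 for pre 1 and post 2 and 0.31 for pre 2 and post 1. They were 0.44 for pre 4 and post 3 and 0.2 for pre 3 and post 4. Over all genes the correlations therefore show earlier against later experiments, and not the pairing by experiment. Some genes did follow single experiments. The mean log2 value of the sterol synthesis list was 7.08 in pre 4 and in post 4. It was 6.31 to 6.45 in the other pre libraries and 6.31 to 6.57 in the other post libraries. With the replicate number as a block, the SE of TFAP2A in post against pre went from 0.65 to 0.13. Earlier experiments gave replicates 1 and 2 and the outgroup, and later ones gave replicates 3 and 4. Fate-specific genes were those called in post against pre and, in the same direction, in post against the outgroup.

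The comparisons, tests, lists, thresholds and the rule for named genes were set before the data were examined. The rule took 25 anchor genes, with POU5F1 and SOX2 among them as a gate check. In each comparison it took the 10 called genes with the largest increase and the 10 with the largest decrease. These came from genes whose groups do not overlap and whose mean is at least 5 in the higher group. The rule also took up to 4 called members of each list with the largest change. In the overexpression libraries it took the transgene and the 5 largest differences in each direction, among genes above or below every other library. These genes needed a symbol and a value of at least 10 in the library itself or in the mean of the others.

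Alternatives were other pseudocounts, filters and scalings, robust limma, only the compared groups, the replicate number as a block (for post against pre with only these libraries in the fit), batch as a term, the earlier experiments alone, leaving out each library in turn, a fold threshold, an estimated correlation and the self-contained list test fry. Added after the data were seen were 1 row per symbol, the experiment as a random effect, leaving out experiment 1 or 3, a block with the outgroup kept or with experiment 3 left out, and the later experiments alone. The pipeline was tested on simulated data with known changes and independent noise in each library, without an effect of experiment or period. The shares found there do not show the power or false calls of either fit, with or without the block, on the real libraries. For post against pre, limma recovered 50.7% of changes of 1 and 93.9% of changes of 2 on the log2 scale, with 2 false among 100 calls, and with the block it recovered 11.9% and 92.4%, with 2 false among 71.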

Results

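Polyadenylated RNA was measured in H1 cells, an established human embryonic stem cell (hESC) line, with fluorescent reporters of OCT4 (the product of POU5F1) and SOX2. Cells were directed to ectoderm in medium with 0.5 µM A83-01, an inhibitor of the Activin and Nodal receptors, and sorted on the ratio of the OCT4 reporter to the SOX2 reporter. The top 10 to 15% gave 4 libraries from before the loss of mesendoderm competence (pre), and the bottom 10 to 15% gave 4 libraries from after it (post). Pre and post libraries with the same replicate number came from the same numbered experiment. The mesendoderm outgroup, treated with BMP4 and Activin A, gave 3 libraries from 3 other experiments and was not sorted. A further 5 libraries came from cells given POU2F3, TFAP2A, GRHL1, JUNB or TFAP2C by lentivirus before mesendoderm differentiation, with 1 library each and no control library.

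The deposited values are abundances per gene on the TPM scale. They are not read counts, so the number of reads per library is unknown and no counting intervals are given. The values summed to between 863663 and 1104242 per library in the 11 libraries of the 3 groups, and to between 917346 and 944422 in the 5 overexpression libraries. Pre replicate 1 held 16.6% of its sum in 10 genes, with the non-coding RNA AL135790.1 at 93338, while the other libraries of the 3 groups held 6.57 to 11.8% in their own top 10. The first principal component, with 50.6% of the variance, separated the outgroup from the sorted libraries. The next, with 18.7%, had positive scores for pre and post replicates 1 and 2 and negative scores for replicates 3 and 4, which came from later experiments. Abundances are given as mean ± SD, folds as ratios of mean abundances, and log2 fold changes as differences of mean log2(value + 1). Limma p-values rest on replicates that, within a group, came from separate numbered experiments, and the main fit does not use the pairing of pre and post. Camera compares the genes of a list with all other genes. At the preset correlation its p-values do not measure the spread between replicates.

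Comparing post with pre asks which genes change as ectoderm-directed cells lose the competence to form mesendoderm. Both groups were fractions sorted by the reporter ratio. Genes said to fall or rise are lower or higher in post than in pre, and no cells were followed over time. After the loss, TDGF1, which encodes the Nodal co-receptor Cripto, fell 16-fold, from 309 ± 38.9 to 19.3 ± 8.42 (n = 4 in each group). The pluripotency factor NANOG fell 12.3-fold and EOMES, a T-box factor of the primitive streak, fell 7.43-fold. The epithelial adhesion genes CDH1 and EPCAM fell 3.62-fold and 5.82-fold, while VIM, an intermediate filament gene of mesenchymal and neural precursor cells, rose 2.65-fold. LHX2 and VAX1, homeobox genes of the early forebrain and eye field, rose 7.41-fold and 11-fold, and the LIM-only gene LMO1 rose 8.71-fold. Of 21015 genes tested with limma, 1127 were called at an adjusted p under 0.05, 419 higher and 708 lower in post, and 354 of them changed by at least 1 on the log2 scale.

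The reporters of the gate were checked first. POU5F1 (chromosome 6, 31164337 to 31180731, hg38) had 1090 ± 215 in pre and 512.5 ± 75.9 in post, a log2 fold change of -1.08 (SE 0.15, limma adjusted p = 0.00271). SOX2 (chromosome 3, 181711924 to 181714436) had 163 ± 33.6 in pre and 221.1 ± 36.3 in post, which limma did not call (log2 fold change 0.45, SE 0.24, adjusted p = 0.36). Both genes set the gate, so their difference checks the sort and is not a separate result. POU5F1 lost its call within the earlier experiments (adjusted p = 0.0865).

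Genes of undifferentiated hESCs fell as a list: of 26 tested, 8 were lower and 0 higher, and 13 were lower and 1 higher when adjusted over the list alone. Camera, a competitive list test, gave an adjusted p = 6.24e-07, with adjusted p = 0.0349 with an estimated correlation. TDGF1 (chromosome 3, 46574534 to 46582463) fell by 4.02 on the log2 scale (SE 0.26, limma adjusted p = 7.94e-05), and NANOG fell by 2.46 (SE 0.18, limma adjusted p = 7.94e-05). GDF3, a Nodal-related ligand, fell by 1.36 and the sialomucin gene PODXL by 1.06; the call of GDF3 rested on post replicate 1, without which its limma adjusted p = 0.0611. Not all of the list moved: 18 of its members were not called. The gate selected cells on the OCT4 reporter, so lower pluripotency genes in post cannot be told apart from that selection.

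Neural ectoderm genes rose: 8 of 22 tested were higher and 0 lower, and 10 were higher when adjusted over the list alone (camera adjusted p = 6.95e-09, and adjusted p = 0.0349 with an estimated correlation). LHX2 (chromosome 9, 124001670 to 124033301) rose from 7.61 ± 3.64 to 56.4 ± 15.6, a log2 fold change of 2.77 (SE 0.28, limma adjusted p = 0.000526). PAX6, a neural progenitor factor, rose from 0.225 ± 0.16 to 1.89 ± 0.994, a low level (limma adjusted p = 0.0167, and 0.0503 without pre replicate 2). SIX3, a factor of the anterior neural plate, rose by 1.34, a call that limma did not make without pre replicate 2 (adjusted p = 0.0559), post replicate 1 (0.0689) or post replicate 4 (0.061). Among neural anchors that limma did not call, OTX2 differed by 0.15 (adjusted p = 0.728), ZIC1 by 0.58 (adjusted p = 0.138) and SOX3 by -0.80 (adjusted p = 0.265, and 0.0276 without pre replicate 1).

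Many epithelial genes fell, and some mesenchymal genes rose while 14 of 21 were not called. Of 20 epithelial genes, 11 were lower and 0 higher, and 17 were lower when adjusted over the list alone (camera adjusted p = 2.76e-14, but adjusted p = 0.0992 with an estimated correlation). CDH1 went from 165 ± 28.9 to 45.5 ± 12.2 and EPCAM from 124 ± 40.8 to 21.3 ± 7.04. The tight junction gene CLDN7 fell by 2.92 on the log2 scale, the splicing factor ESRP1 by 2.15 and the epithelial transcription factor GRHL2 by 2.43 (limma adjusted p = 0.00169, 0.000144 and 0.00169). Of 21 mesenchymal genes, 7 were higher and 0 lower, and 9 were higher and 1 lower when adjusted over the list alone, with a median log2 fold change of 0.09 (camera adjusted p = 0.00131, and adjusted p = 0.043 with an estimated correlation). VIM rose from 163 ± 37.7 to 432 ± 11.4, the cadherin gene CDH11 by 1.25 and the transcriptional repressor ZEB1 by 1.47 on the log2 scale (limma adjusted p = 0.000544, 0.00058 and 0.0121).

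**Figure D1:**
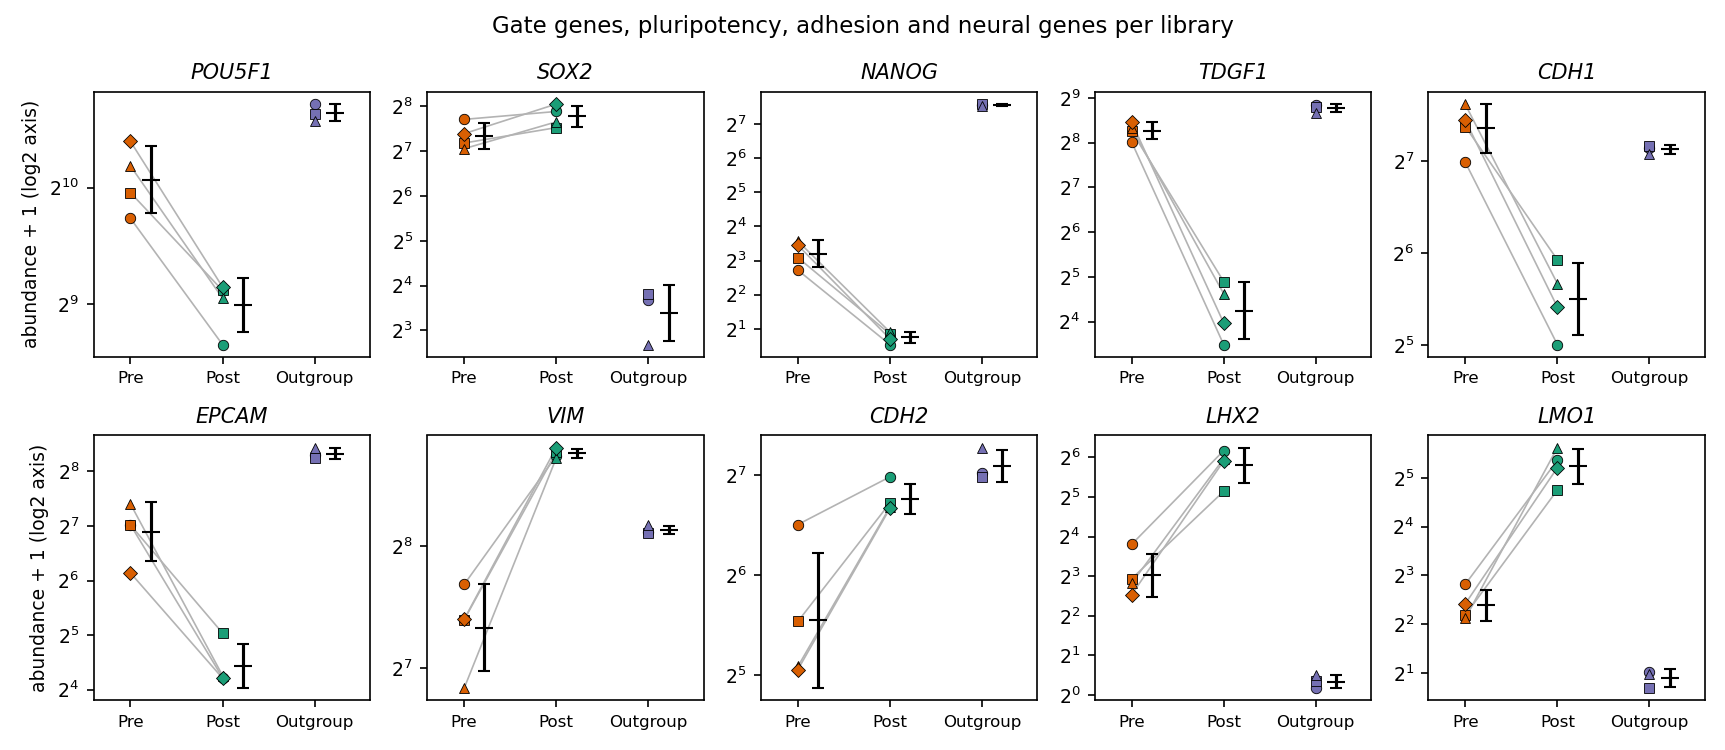
Abundance of 10 genes in the 4 pre, 4 post and 3 outgroup libraries, plotted as value + 1 on a log2 axis, with a point per library shaped by replicate number (outgroup shapes do not pair with the others), a grey line joining the pre and post libraries of an experiment, and a bar at the mean ± SD of the log2 values. TDGF1, NANOG, CDH1 and EPCAM were lower in every post library than in every pre library, and VIM, LHX2 and LMO1 were higher.

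Some surface ectoderm and amnion genes were lower in post, with a wide spread between experiments. Of 19 surface ectoderm genes, 3 were lower and 0 higher, and 6 were lower when adjusted over the list alone (camera adjusted p = 5.4e-07, but adjusted p = 0.344 with an estimated correlation). The 3 were GRHL2, the placode factor FOXI3 and the epidermal repressor OVOL1. The call of FOXI3 was lost without post replicate 1, 2 or 4 (limma adjusted p = 0.0915, 0.0698 and 0.0892), and that of OVOL1 was lost with the replicate number as a block (0.0607). Of 12 amnion and trophoblast genes, 2 were lower and 1 higher, and 5 were lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00371, but adjusted p = 0.344 with an estimated correlation). GABRP, a subunit of a GABA receptor expressed in amnion, fell from 37.9 ± 5.59 to 15.8 ± 3.83. Limma did not call TFAP2A (log2 fold change -1.33, adjusted p = 0.298) or GATA3 (-1.87, adjusted p = 0.151), but it called both with the replicate number as a block (adjusted p = 0.0114 and 0.0121). TFAP2C at -1.40 (adjusted p = 0.0741) was called without pre replicate 3 (adjusted p = 0.0283) or pre replicate 4 (0.0463), and HAND1 at -1.65 (adjusted p = 0.199) was not called without any single library. Pre replicate 3 stood apart in these lists, with a mean log2 value of 3.85 over the amnion genes against 2.31 to 2.43 in the other pre libraries, and 4.88 against 3.24 to 3.59 over the surface ectoderm genes.

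**Figure D2:**
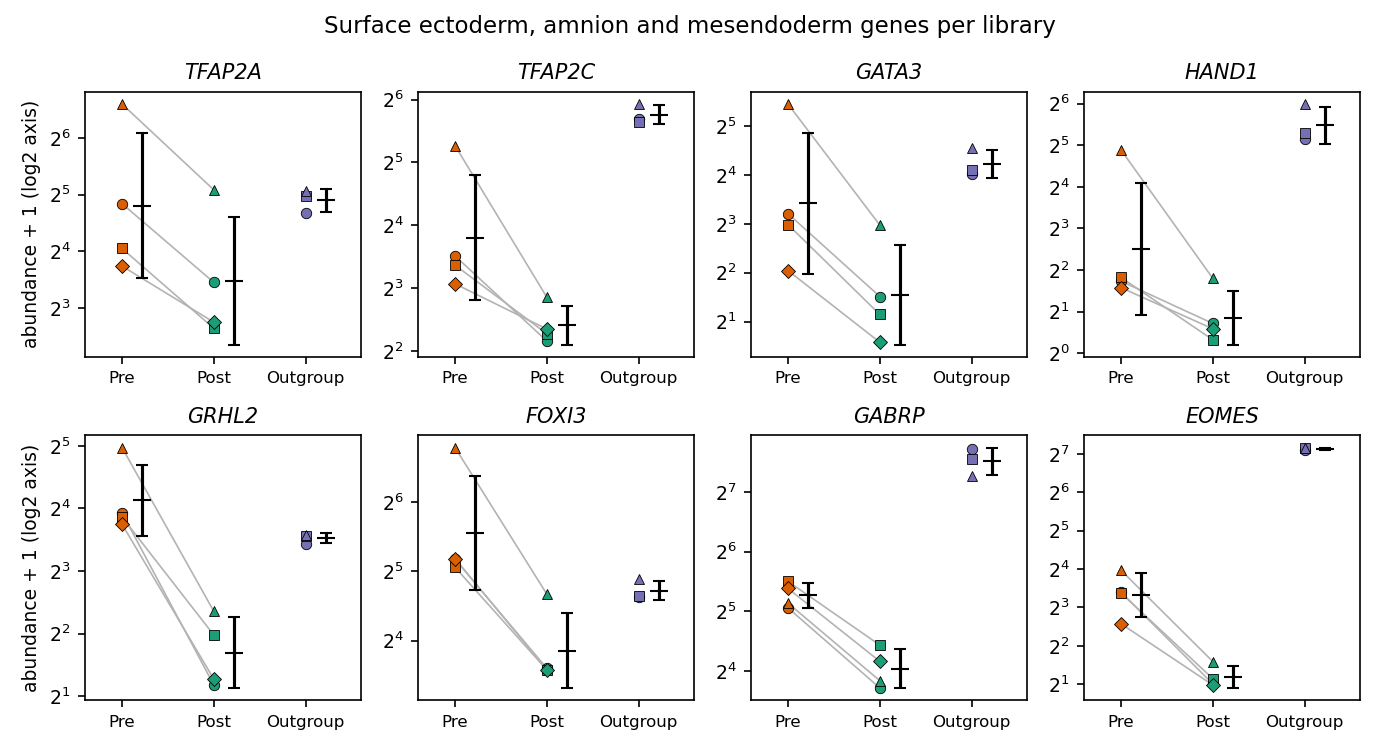
Abundance of 8 genes of surface ectoderm, amnion and the primitive streak in the same libraries and with the same symbols. Pre replicate 3 was the highest of the 4 pre libraries for HAND1, at 28.6, for GRHL2, at 30.4, and for FOXI3, at 109.1.

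Of 20 Nodal pathway genes 2 were lower (TDGF1 and GDF3), and of 17 streak genes 2 were lower (EOMES and APELA), with 0 higher in either list and the same counts when adjusted over the list alone, and camera called neither list (adjusted p = 0.0704 and 0.46). APELA, which encodes a ligand of the apelin receptor, fell from 10.6 to 1.77 (limma adjusted p = 0.028), a call lost with the block (0.0869) and without post replicate 1, 2, 3 or 4 (0.0904, 0.0561, 0.0625 and 0.0639). Several other mesendoderm genes were near the floor in both sorted groups, which both came from medium with the receptor inhibitor A83-01. MIXL1 had 0.547 ± 0.194 in pre and 0.344 ± 0.111 in post, TBXT had 0.485 ± 0.471 and 0.208 ± 0.0738, and GATA6 had 0.357 ± 0.474 and 0.0864 ± 0.0487, none of them called by limma (adjusted p = 0.428, 0.582 and 0.521). SOX17 averaged 0.0888 in pre and was listed at 0 in every post library. NODAL differed by -0.09, LEFTY1 by -0.04 and LEFTY2 by -0.05 (limma adjusted p = 0.886, 0.883 and 0.886). CDH5, TIE1 and LMO2, genes of endothelial and blood precursors, rose: 3 of 9 list members were higher and 0 lower, and 4 were higher when adjusted over the list alone (camera adjusted p = 0.000327, but adjusted p = 0.0524 with an estimated correlation). CDH5, which encodes VE-cadherin, reached 4.50 ± 0.618 from 0.703 ± 0.0725.

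Of the families of the overexpressed factors, 3 of 16 genes were lower and 1 higher, and 6 were lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00139, but adjusted p = 0.342 with an estimated correlation). This list was built here from the families of the 5 factors that the study chose to overexpress. The study may have chosen these factors in part from its own data, so the count is not independent evidence. GRHL2, FOSL1 and ATF3 fell and JUN rose from 4.92 ± 2.14 to 17.6 ± 3.32 (limma adjusted p = 0.00493). GRHL1 at -0.36, POU2F3 at -0.42 and JUNB at -0.63 were not called (limma adjusted p = 0.421, 0.419 and 0.283, with JUNB at 0.0399 without pre replicate 1). Immediate early genes, which respond to dissociation and sorting, had 1 of 15 higher and 2 lower, and 1 higher and 3 lower when adjusted over the list alone. Camera gave adjusted p = 0.0219, but adjusted p = 0.415 with an estimated correlation. The list was not called without pre replicate 3 (camera adjusted p = 0.121) or post replicate 2 (0.0546). With the replicate number as a block, limma also called FOS at -1.41 and EGR1 at -1.4 lower (adjusted p = 0.0156 and 0.0141). JUN stayed called higher with the block (limma adjusted p = 0.0241).

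Lists of p53 targets and of proliferation genes were lower as lists although limma called 0 of their 16 and 25 members, with 6 and 5 members at an unadjusted p under 0.05. Adjusted over the list alone, 2 p53 targets and 0 proliferation genes were lower. Camera gave adjusted p = 0.000222 for p53 targets, but adjusted p = 0.16 with an estimated correlation. Camera gave adjusted p = 0.0219 for proliferation, but adjusted p = 0.344 with an estimated correlation, and the list was not called without pre replicate 1 (adjusted p = 0.109), pre replicate 3 (0.0821) or post replicate 4 (0.0569). With quantile normalization its median changed sign, from -0.15 to 0.01 (camera adjusted p = 0.692). The other 13 lists (Nodal pathway, primitive streak, endoderm, mesoderm, neural crest, Wnt, BMP, FGF and ERK, Notch, hypoxia and glycolysis, sterol synthesis, DNA methylation and Polycomb, mitochondrial RNA) had camera adjusted p from 0.0558 to 0.779. For neural crest, sterol synthesis and DNA methylation with Polycomb genes, the median and the mean had opposite signs. With the replicate number as a block, camera at the preset correlation also called the Nodal pathway, mesoderm and BMP lists, all lower (adjusted p = 0.0132, 0.00436 and 0.0288). Without the block these lists had adjusted p = 0.342, 0.741 and 0.874 with an estimated correlation, which was not run with the block.

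The 10 largest increases that separated the groups also held FOXB2, GREB1L, FLRT3, DLK1 and SSTR2, at log2 fold changes of 1.89 to 2.32. The 5S pseudogenes RNA5SP317 and RNA5SP311 were in it too, but they hold identical values in every library, so their reads cannot be told apart. The 10 largest decreases also held PCAT14, FOXD3-AS1, SERPINB9, ANO1, LINC00678 and MCOLN3, at -3.26 to -2.44. FOXD3, a stem cell and neural crest factor, fell from 5.27 ± 3.87 to 0.138 ± 0.112, a call lost without experiment 3 (limma adjusted p = 0.067). The call of PCAT14 was lost without post replicate 1, 2 or 4 (limma adjusted p = 0.0727, 0.0543 and 0.0677), and that of the 5S pseudogenes without pre replicate 2 (0.0515) or post replicate 4 (0.0613).

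The groups did not overlap for 2502 genes, 11.9% of those tested, against 2.86% by chance, and 4057 genes had an unadjusted p under 0.05. With only the pre and post libraries in the fit 453 genes were called, and 537 when the replicate number was added as a block, 483 of them among the 1127. With the outgroup kept in the fit the block gave 1855. Within the earlier experiments (replicates 1 and 2) 88 genes were called, within the later ones (replicates 3 and 4) 758, and with experiment batch as a term 1772. The fits within the earlier and the later experiments kept the outgroup libraries. Within the earlier and the later experiments the log2 fold changes were -3.95 and -4.10 for TDGF1 post against pre, 2.56 and 3.15 for LMO1 post against pre, -1.72 and -1.99 for CDH1 post against pre, and 2.29 and 3.26 for LHX2 post against pre. Limma called all of these within the later experiments (adjusted p = 0.000819, 0.00142, 0.000924 and 0.000892), but CDH1 and LHX2 not within the earlier ones (0.0688 and 0.0712). TDGF1 and LMO1 were the 2 of 61 named and called genes that limma called under every alternative, and 55 of the 61 were called with the block. Without experiment 3, 489 genes were called, and 3 with the block as well. The count was 2122 without pre replicate 1, 646 without pre replicate 2, 687 without pre replicate 3, 447 without post replicate 1, 529 without post replicate 4 and 727 without outgroup replicate 2. Median-of-ratios scaling moved the split of calls from 37.2% to 49.1% higher.

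Comparing the outgroup with pre describes the mesendoderm branch, along with differences in medium, experiment and sorting. Pre cells were in medium with A83-01, the inhibitor of the Activin and Nodal receptors, and the outgroup was given Activin A. Differences in Nodal pathway genes therefore cannot be told apart from the medium. The outgroup expressed the Nodal antagonist gene CER1 (chromosome 9, 14719724 to 14722717) at 2309 ± 78.8 (n = 3), against 0.0153 ± 0.0177 in pre. The streak factor MIXL1 reached 366 ± 26.6, the endoderm factor SOX17 89.8 ± 11.4, and the Nodal inhibitor gene LEFTY2 224.8 ± 26.6, all under 1 in pre. NANOG rose 22.2-fold to 187.7 ± 3.09, while SOX2 fell 16.1-fold to 10.1 ± 4.15. Among the genes that fell, HESX1 went from 86.3 ± 39.1 to 1.55 ± 0.508, LHX5 from 35.6 ± 7.68 to 0.0657 ± 0.00505, and the Wnt inhibitor gene SFRP1 fell 27.5-fold. Limma called 5484 genes, 3001 higher and 2483 lower in the outgroup, and 2337 of them changed by at least 1 on the log2 scale.

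Of 17 primitive streak genes 13 were higher and 0 lower, the same numbers when adjusted over the list alone (camera adjusted p = 8.13e-12, and adjusted p = 0.0149 with an estimated correlation). MIXL1 rose by 7.90 on the log2 scale, TBXT by 4.77 and EOMES by 3.80. Of 20 Nodal pathway genes 11 were higher and 0 lower, and 12 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 3.87e-07, and adjusted p = 0.0149 with an estimated correlation). CER1 rose by 11.15 (SE 0.1, limma adjusted p = 1.77e-13), LEFTY1 by 7.10 and NODAL by 5.01. Of 11 endoderm genes 7 were higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 5.24e-07, but adjusted p = 0.0992 with an estimated correlation), with SOX17 up by 6.38, GATA6 by 4.61 and CXCR4 by 4.34. Of 13 mesoderm genes 9 were higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.0398, but adjusted p = 0.684 with an estimated correlation). That list was not called without pre replicate 1 (adjusted p = 0.218), pre replicate 2 (0.0543) or pre replicate 4 (0.102). ACTC1, a cardiac actin gene, rose by 1.71, and HAND1 rose by 2.98 (limma adjusted p = 0.0103, and 0.0509 without outgroup replicate 3).

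Of 22 neural ectoderm genes 17 were lower and 2 higher, and 18 were lower and 2 higher when adjusted over the list alone (camera adjusted p = 3.85e-10, and adjusted p = 0.0149 with an estimated correlation). SIX3 fell by 3.37 and FEZF1 by 4.42, while CDH2, which encodes N-cadherin, rose by 1.55. PAX6 was at 0.165 ± 0.101 in the outgroup and 0.225 ± 0.16 in pre (limma adjusted p = 0.88). Pluripotency genes went both ways, with 5 higher and 12 lower of 26, and 5 higher and 16 lower when adjusted over the list alone (camera adjusted p = 0.00429, but adjusted p = 0.0992 with an estimated correlation). NANOG, GDF3 and FGF4 rose by 4.35, 2.47 and 2.99, and the DNA methyltransferase gene DNMT3B and the nuclear receptor gene NR5A2 fell by 1.63 and 2.48. POU5F1 rose by 0.57 (limma adjusted p = 0.0245), a call lost without pre replicate 2 (0.06) or outgroup replicate 1, 2 or 3 (0.0935, 0.0738 and 0.0598). DNA methylation and Polycomb genes had 8 of 19 lower and 0 higher, and 9 lower when adjusted over the list alone (camera adjusted p = 0.000222, and adjusted p = 0.0149 with an estimated correlation), with the Polycomb cofactor JARID2 down by 1.53.

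Hypoxia and glycolysis genes had 12 of 20 higher and 0 lower, also when adjusted over the list alone (camera adjusted p = 7.35e-05, but adjusted p = 0.189 with an estimated correlation). LDHA, which encodes lactate dehydrogenase, rose from 366 ± 49.4 to 1565 ± 68.9, and BNIP3, a mitophagy gene, rose by 2.96. Mitochondrial messenger RNAs had 8 of 13 lower and 0 higher, and 9 lower when adjusted over the list alone (camera adjusted p = 8.28e-05, but adjusted p = 0.43 with an estimated correlation). Their share of the summed values was 3.22 to 4.97% in the outgroup, 5.05 to 6.78% in pre and 5.82 to 7.57% in post, and only the pre and post cells were sorted. FGF and ERK genes had 4 of 20 higher and 8 lower, and 4 higher and 9 lower when adjusted over the list alone (camera adjusted p = 0.0151, but adjusted p = 0.18 with an estimated correlation). FGF8 rose by 4.35, while the ERK phosphatase genes DUSP6 and DUSP4 fell by 3.11 and 2.82.

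The amnion list had 6 of 12 higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.0398, but adjusted p = 0.537 with an estimated correlation). It was not called without pre replicate 1 (adjusted p = 0.141), pre replicate 2 (0.0591) or pre replicate 4 (0.0867), and pre replicate 3 stood apart in it. GABRP rose 4.83-fold and TFAP2C by 1.95 on the log2 scale, while TFAP2A at 0.10 and GATA3 at 0.80 were not called (limma adjusted p = 0.941 and 0.472). Immediate early genes had 5 of 15 higher and 0 lower, and 6 higher when adjusted over the list alone (camera adjusted p = 0.0398, but adjusted p = 0.537 with an estimated correlation). That list was not called without pre replicate 1 (adjusted p = 0.14), pre replicate 2 (0.0543), pre replicate 4 (0.0867) or outgroup replicate 3 (0.0554). With pre and post from the later experiments only, camera did not call the mesoderm, amnion, immediate early and FGF and ERK lists (adjusted p = 0.383, 0.331, 0.297 and 0.0502). p53 targets had 1 of 16 higher and 5 lower, also when adjusted over the list alone (camera adjusted p = 0.0061, but adjusted p = 0.25 with an estimated correlation), with the death receptor gene FAS down by 1.53. The other 11 lists (endothelial and blood, surface ectoderm, neural crest, epithelial, mesenchymal, Wnt, BMP, Notch, proliferation, sterol synthesis, and the families of the overexpressed factors) had camera adjusted p from 0.114 to 0.966. CDH1 was at 139 ± 4.8 in the outgroup against 165 ± 28.9 in pre, which limma did not call (adjusted p = 0.467), and EPCAM rose 2.59-fold. For the endothelial and Notch lists the median and the mean had opposite signs, and camera put the surface ectoderm list lower although its median and mean were positive.

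**Figure D3:**
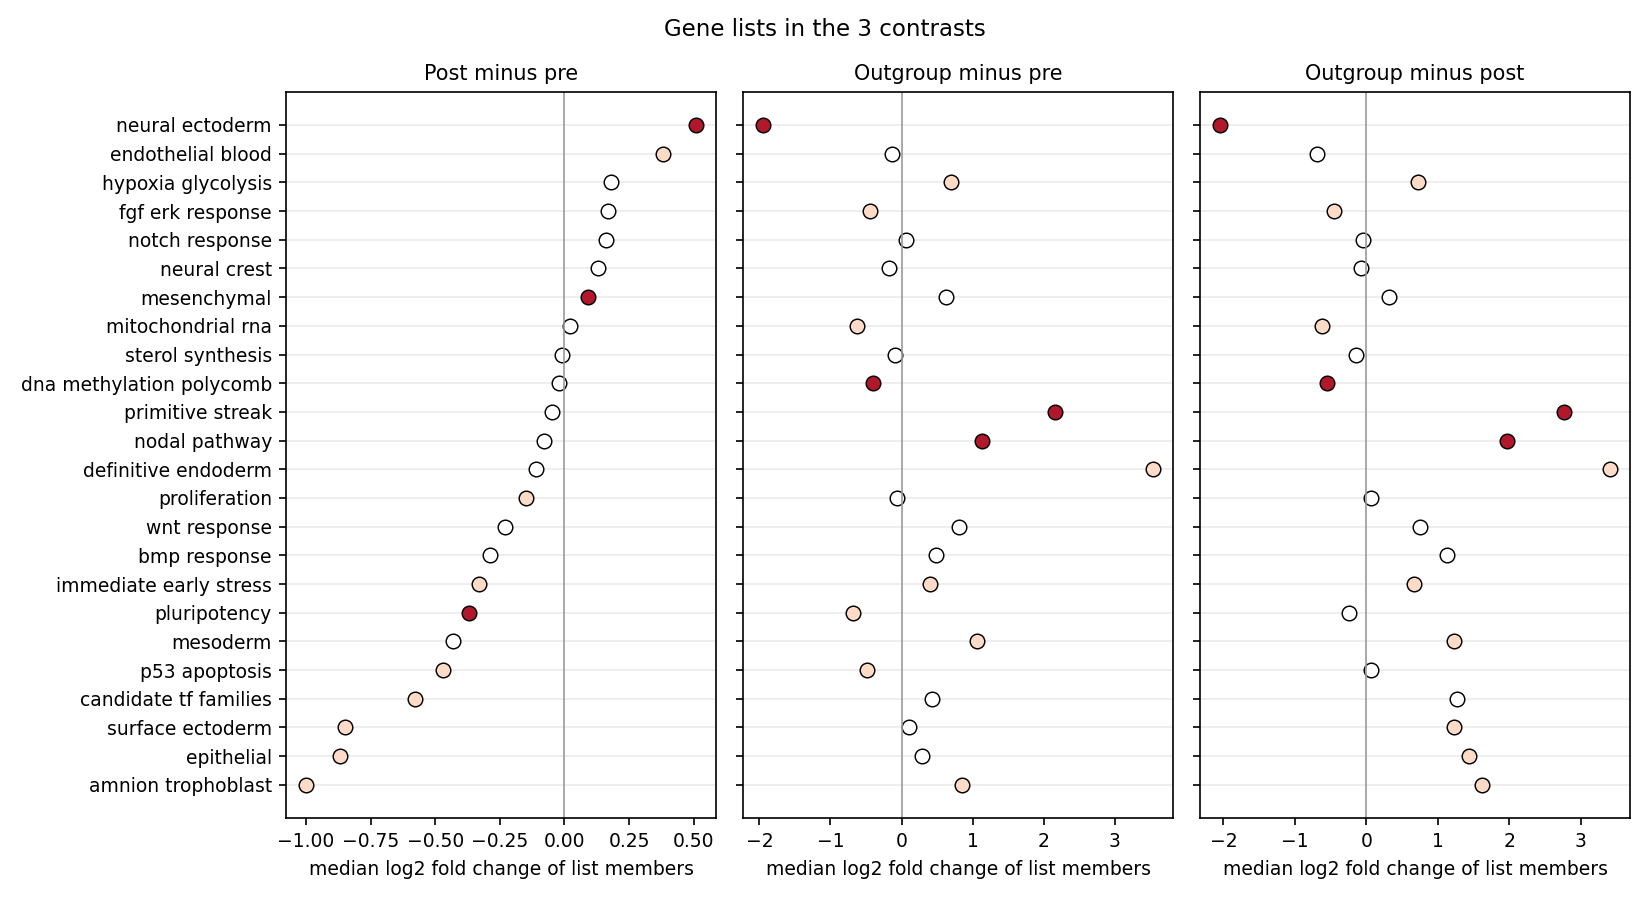
Median log2 fold change of the 24 gene lists with enough tested members, in each of the 3 comparisons. Dark red marks lists called by camera with the preset and with an estimated correlation, pale red those called with the preset correlation alone, and white those not called.

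The largest increases also included PCDH10, MFAP4 and GAL, at log2 fold changes of 6.09 to 6.40, and the largest decreases included RIPPLY3 at -6.29, LGI1 at -5.00, PKDCC at -4.89 and SHISA2 at -4.69. The groups did not overlap for 7377 genes, 35.1% of those tested, against 5.71% by chance, and 7733 genes had an unadjusted p under 0.05. Outgroup and pre libraries came from different experiments, and the later experiments held no outgroup library. With the earlier experiments alone 5081 genes were called, and 5918 with batch as a term. Quantile normalization moved the split of calls from 54.7% to 46.1% higher, with 2707 higher and 3163 lower. The count was 3468, 3508 and 3518 without outgroup replicate 1, 2 and 3.

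Comparing the outgroup with post sets the fates against each other, along with differences in medium, experiment and sorting. TDGF1 was 22.6-fold and NANOG 272-fold higher in the outgroup, which had 436 ± 27.7 and 187.7 ± 3.09. CLDN7 was 26-fold, EPCAM 15.1-fold and CDH1 3.05-fold higher in the outgroup. LHX2 was 209-fold higher in post, at 56.4 ± 15.6 against 0.270 ± 0.136, and the chondrogenic and neural crest factor SOX9 was 68.2-fold higher, at 77.9 ± 10.3 against 1.14 ± 0.187. SOX17, at 89.8 ± 11.4 in the outgroup, was listed at 0 in every post library. Limma called 7140 genes, 4091 higher and 3049 lower in the outgroup, and 3039 changed by at least 1 on the log2 scale.

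Lists with their camera call held under an estimated correlation were primitive streak (14 of 17 higher), Nodal pathway (14 higher and 2 lower of 20), neural ectoderm (1 higher and 19 lower of 22) and DNA methylation and Polycomb genes (12 of 19 lower). Their camera adjusted p was 6.07e-11, 1.84e-07, 2.19e-12 and 0.000175, and each had an adjusted p = 0.0137 with an estimated correlation. Adjusted over the list alone, 15 streak genes were higher, 14 Nodal genes higher and 2 lower, 1 neural gene higher and 19 lower, and 12 methylation and Polycomb genes lower. Epithelial genes had 14 of 20 higher and 0 lower, and 15 higher when adjusted over the list alone (camera adjusted p = 3.21e-05, but adjusted p = 0.378 with an estimated correlation). Endoderm genes had 8 of 11 higher and 0 lower, and 9 higher and 1 lower when adjusted over the list alone (camera adjusted p = 2.92e-07, but adjusted p = 0.109 with an estimated correlation). Mesoderm genes had 9 of 13 higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.0162, but adjusted p = 0.622 with an estimated correlation).

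Surface ectoderm genes had 11 of 19 higher and 1 lower, and 11 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.0162, but adjusted p = 0.675 with an estimated correlation). Amnion genes had 7 of 12 higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.00402, but adjusted p = 0.378 with an estimated correlation). TFAP2C was higher by 3.35 on the log2 scale and GRHL2 by 1.83 (limma adjusted p = 0.000128 and 0.00159), while TFAP2A at 1.42 was not called (adjusted p = 0.147, and 0.036 without post replicate 3). FGF and ERK genes had 4 of 20 higher and 9 lower, and 4 higher and 11 lower when adjusted over the list alone (camera adjusted p = 0.00858, but adjusted p = 0.172 with an estimated correlation). Immediate early genes had 7 of 15 higher and 1 lower, and 8 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00823, but adjusted p = 0.378 with an estimated correlation), with KLF6 higher by 2.25 and ATF3 by 1.66. Hypoxia genes had 13 of 20 higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.00087, but adjusted p = 0.324 with an estimated correlation). Mitochondrial messenger RNAs had 8 of 13 lower and 0 higher, and 10 lower when adjusted over the list alone (camera adjusted p = 0.000169, but adjusted p = 0.426 with an estimated correlation). The other 11 lists had camera adjusted p from 0.055 to 0.835, and the pluripotency list, with 7 of 26 higher and 9 lower, had a median of -0.25 and a mean of 0.36. The p53 list had a median and a mean of opposite signs as well. With pre and post from the later experiments only, camera did not call the mesoderm, surface ectoderm and amnion lists (adjusted p = 0.15, 0.204 and 0.0941).

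The groups did not overlap for 10540 genes, 50.1% of those tested, against 5.71% by chance, and 8995 genes had an unadjusted p under 0.05. With the earlier experiments alone 5824 genes were called, and 7521 with batch as a term. Quantile normalization moved the split of calls from 57.3% to 46.7% higher.

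The outgroup was included so that changes specific to a fate could be found. It also differed from post in medium, in experiments and in not being sorted, so a call against it cannot tell fate apart from these. Of the 1127 genes called between post and pre, 821 were also called in the same direction between post and the outgroup, 321 higher and 500 lower in post than in both. All 11 epithelial genes that fell in post were among them, with CDH1, EPCAM, CLDN7, ESRP1 and GRHL2. So were 6 neural and 6 mesenchymal genes that rose, such as LHX2, PAX6, ZEB1 and CDH11, and the 3 endothelial genes CDH5, TIE1 and LMO2. TDGF1, NANOG and GDF3 were lower in post than in both, whereas 4 other pluripotency genes, PODXL among them, fell in both branches. Of the 821 genes, 430 had moved the opposite way between outgroup and pre, as NANOG and LHX2 did, 379 were not called there, as was so for TDGF1, CDH1 and GRHL2, and the rest had moved the same way.

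Of the 1127 genes, 65 were higher and 158 lower than pre in both branches; a few of them, such as VIM, FLRT3 and FOXD3-AS1, were also among the 821. ANO1, MCOLN3, FOSL1 and JARID2 fell in both, and CDH2 and CXCR4 rose in both. Independent lists of these sizes would share 143.5 genes in the same direction and 150.6 in opposite directions, against these 65 and 158 together and 430 observed. With the pre libraries split between the comparisons, 65 to 161 genes were shared in the same direction and 123 to 446 in opposite directions. Across genes, which are not independent replicates, the fold changes of the branches correlated at -0.086, against 0.464 for simulated unchanged groups and -0.346 to -0.11 with the split, with a covariance of -0.027 against 0.035 simulated. For the 821 genes the independent value was 198.6, and with the post libraries split between the comparisons 62 to 167 genes were higher and 117 to 247 lower. The correlation there was 0.502 against 0.46 simulated and 0.162 to 0.407 with the split, and the covariance 0.182 against 0.035. The count was 78 with the earlier experiments alone, 596 with the later ones and 376 without experiment 3. It was 1479 without pre replicate 1, 487 without pre replicate 2, 516 without pre replicate 3, 351 without post replicate 1, 400 without post replicate 4 and 533 without outgroup replicate 2.

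In the overexpression libraries each delivered factor stood above its level in the other 4 libraries. POU2F3 was at 524 in its library against 0.4 to 1.7 in the others, GRHL1 at 513 against 2.2 to 3.6, JUNB at 408 against 6.1 to 7.9, TFAP2A at 358 against 9.5 to 47.8, and TFAP2C at 295 against 20.1 to 64.0. All 5 had mesendoderm transcripts, with MIXL1 at 306 to 634, EOMES at 244.9 to 321.4, SOX17 at 178.7 to 239.2 and SOX2 at no more than 0.7. GRHL2 was at 20.9 in the POU2F3 library and at 1.3 to 2.8 in the others. These are single libraries with no control, so no difference among them has a replicate check, and the table was scaled apart from the other one, so no value is set against the 3 groups.

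Lists were described by the median difference of a library from the mean of the 4 others, on the log2(value + 1) scale, and its percentile among 10000 random lists matched on size and expression. The mean of the others holds every other overexpression library, so a shift in a library moves the rest the opposite way by construction. Random lists were drawn gene by gene, without the correlation between genes that a fixed list can have. A percentile near 0 or 100 is therefore not evidence of an effect of the factor. Mitochondrial messenger RNAs, with an estimated correlation of 0.772 in the 3 groups, reached percentile 0 in the TFAP2A and 100 in the JUNB library. In the POU2F3 library the amnion list had a median of -0.87 and the Wnt list -0.54, both at percentile 0, surface ectoderm had -0.41 (percentile 0.19) and HOX genes -0.73 (0.21). BMP, epithelial and mesenchymal genes were at -0.29, -0.28 and -0.24 there (percentiles 0.74, 0.67 and 0.68). In the GRHL1 library HOX genes were at 0.99 (percentile 99.98), amnion at 0.61 (99.91), surface ectoderm at 0.56 (100), endoderm at 0.34 (99.32), BMP at 0.32 (99.92), streak at 0.28 (99.48) and epithelial genes at 0.26 (99.58). In the TFAP2A library neural genes were at -0.50 (percentile 0), BMP genes at -0.28 (0.01), streak genes at -0.27 (0.1) and mitochondrial messenger RNAs at -0.24 (0), with proliferation genes at 0.15 (99.56). In the JUNB library neural genes were at 0.31 (percentile 99.67), mitochondrial messenger RNAs at 0.28 (100), mesenchymal genes at 0.24 (99.95), BMP genes at 0.19 (99.42) and surface ectoderm at -0.21 (0.57). The TFAP2C library had surface ectoderm at -0.29 (percentile 0.18) and Wnt genes at 0.19 (99.71). These are 26 of the 125 medians, picked for a percentile of at most 1 or at least 99. The families of the overexpressed factors, a list built on the study's choice of factors, add a further median. It was -0.68 in the POU2F3 library (percentile 0). The GRHL1 library listed 18813 genes above 0, against 21091 to 22579 in the others. The transgene is itself a member of the surface ectoderm list in all but the JUNB library, and of the amnion list in the TFAP2A and TFAP2C libraries.

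**Figure D4:**
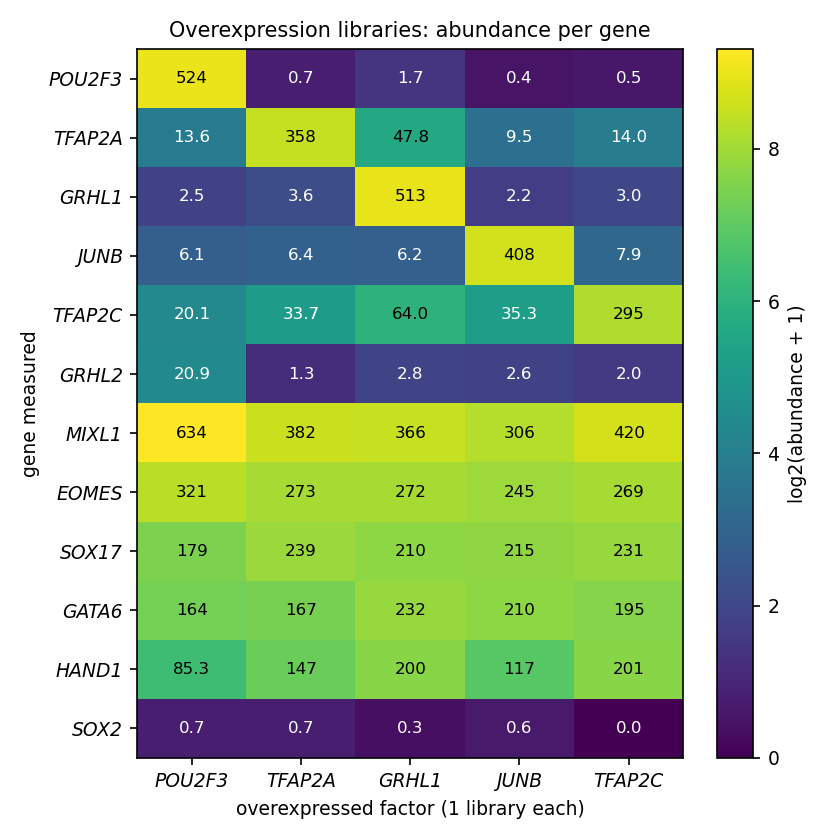
Abundance of 12 genes in the 5 overexpression libraries as a heat map, with the value printed in each cell. Each factor is highest in the library that received it, and SOX2 is at 0.7 or lower in every library.

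The POU2F3, GRHL1 and JUNB transgenes were the genes with the largest positive difference in their libraries. Many of the other extreme genes were pseudogenes, such as RNA5SP323 of the 5S ribosomal RNA and RPL21P16 of a ribosomal protein, whose reads can be shared with near-identical copies, so their differences are uncertain. Others were protein-coding genes, such as NOMO1 and LENG8 in the POU2F3 library, DUOX1 in the TFAP2A library and ZMIZ1 in the TFAP2C library, all lower there than in the others. Differences of at least 2-fold from the mean of the others were seen for 2349 genes in the POU2F3, 1713 in the TFAP2A, 3035 in the GRHL1, 1698 in the JUNB and 1468 in the TFAP2C library, among 19126 genes. The GRHL1 library, with the highest of these counts, also had the lowest estimated relative depth, 0.401 of that of the POU2F3 library against 0.705 to 0.818 in the other 3.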

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

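The tests of experiment 3 in this part were chosen after the results were seen. Dixon's test was applied to 172 groups of 4 values, of named genes and of library measures such as depth. In 13 of them, all of named genes, 1 library was set apart from the other 3. Its gap, relative to the group's range, was larger than Dixon's critical value. Of the 13, 6 were in pre replicate 3. About 1 in 20 such groups is set apart by chance.

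Pre replicate 3 was the highest pre library for the placode gene FOXI3, at 109.1 against 32.3 to 35.3, for HAND1 at 28.6 against 2.0 to 2.5, and for GRHL2 at 30.4 against 12.4 to 14.2. It was also the highest for TBXT at 1.2 against 0.2 to 0.3, for GATA6 at 1.1 against 0.1, and for SOX17 at 0.3 against 0.0. Post replicate 3, from the same experiment, was the highest post library for FOXI3, at 24.4 against 10.9 to 11.1. Post replicate 2 was the highest for EPCAM, at 31.9 against 17.5 to 18.2, for PODXL, at 265.4 against 187.6 to 196.9, and for MCOLN3, at 4.1 against 2.5 to 2.7. Post replicate 1 was the highest for CDH2, at 125.4 against 100.7 to 104.5. Pre replicate 1 was the lowest for IGFBP5, at 0.4 against 0.6 in each of the others, and pre replicate 4 the lowest for PAX7, at 2.6 against 4.5 to 4.9.

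The surface ectoderm and amnion lists, with medians of -0.85 and -1 in post against pre, were highest in experiment 3. The difference was therefore tested without it. The medians were then -0.9 for surface ectoderm and -0.84 for amnion, both called by camera at the preset correlation, and the size of these medians argues against experiment 3 as the only source. With all experiments both lists lost their call with an estimated correlation (adjusted p = 0.344 for each), which was not run without experiment 3. Cells of another type in the pre gate of experiment 3 alone are argued against as well: post replicate 3 was the highest of the 4 post libraries in 20 of the 26 genes of these lists (76.9%, against 38.2% of all genes). BMP response genes in neither list were highest in replicate 3 of both gates in 14 of 19 cases (73.7%, against 12.7% of all genes). A stronger BMP response in the whole culture of experiment 3 is a candidate explanation of its high values. It was found and tested on the same libraries, and BMP activity itself was not measured. Cells of another type present in both gates of that experiment were not tested apart from it. Why these genes are lower in post in the other experiments stays open, and the gate on the reporters is part of the design of every one of them.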

How the results depend on the processing

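Chosen after the data were seen were the experiment as a random effect, the block with the outgroup kept or with experiment 3 left out, leaving out experiment 1 or 3, 1 row per symbol, and the later experiments alone. No called gene reversed under any alternative. Among comparisons of named genes with their alternatives 7519 kept direction and side of the threshold, as did 1806 list comparisons, while 396 and 41 lost the call and 31 and 70 gained it.

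Genes called in post against pre (1127) numbered 354 with a fold threshold, 737 without a filter, 453 with only the 2 groups, 537 with the replicate block on those 2 groups, 1772 with batch as a term, 88 with the earlier experiments only, 2174 with a random effect, 1855 with the block and the outgroup kept, 489 without experiment 3 and 3 with the block as well. Leaving out 1 library gave 447 (without post replicate 1) to 2122 (without pre replicate 1). Fewer libraries leave fewer degrees of freedom in the fits of 2 groups, the block and the earlier experiments. That alone does not account for the counts. The later experiments leave as many libraries in each group as the earlier ones, but gave 758. Outgroup against post rose from 7140 to 9182 with only its 2 groups in the fit. Outgroup libraries, which share the estimate of spread in the main fit, correlated with each other at 0.983 to 0.988. Pre libraries did so at 0.913 to 0.973 and post libraries at 0.951 to 0.983. The cause was otherwise not tested.

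Outgroup against pre (5484) gave 2337 with a fold threshold, 8399 with the later experiments only, which hold no outgroup library of their own, and 3468 (without outgroup replicate 1) to 7323 (without pre replicate 1). Outgroup against post (7140) gave 3039 with a fold threshold and 4888 to 9124 without 1 library. Fate-specific genes (821) were 268 with a fold threshold, 78 with the earlier experiments only, 1426 with a random effect, 1253 with the block and the outgroup kept, 376 without experiment 3, and 351 (without post replicate 1) to 1479 (without pre replicate 1). The cause was not tested.

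Lists called fell from 11 to 3 in post against pre, from 13 to 4 in outgroup against pre and from 13 to 4 in outgroup against post with an estimated correlation. A larger correlation raises the p-values of camera by construction, and no other cause was tested. The preset was 0.01, and the estimates were 0.435 for epithelial, 0.68 for surface ectoderm and 0.772 for mitochondrial genes. Lists that kept their call had estimates of -0.004 to 0.088. The endothelial list, at 0.051, lost its call in post against pre. Fry called 8, 14 and 20. Without 1 library they ranged over 10 to 14, 10 to 14 and 13 to 15.

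The genes that reversed were not called. NODAL in post against pre went from -0.09 to 0.21 with the earlier experiments only and 0.1 without pre and post replicate 3, with -0.34 without pre and post replicate 1. PAX6 in outgroup against pre went from -0.07 to 0.13 with batch as a term, and -0.13 to 0.02 without 1 library. TFAP2A there went from 0.10 to -0.21 with the block, -0.27 with the later experiments only, and -0.26 to 0.69 without 1 library. Outgroup and pre libraries with the same number share no experiment, so in that comparison the block has no pairing behind it. The cause was not tested.

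Transgene differences moved with the pseudocount by construction: at 0.1 and 5, POU2F3 had 9.35 and 6.51, GRHL1 7.48 and 6.05, and JUNB 5.93 and 5.15, against 8.23, 7.08 and 5.75. The number of reads is unknown. Relative depth, estimated from low values, was 0.841 to 2.63 times that of pre replicate 1 in the 3 groups, 2.12 to 2.59 in the outgroup, and lowest in the GRHL1 library among the overexpression libraries (0.401 of the POU2F3 library). Its effect on the counts of genes was not tested.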

Other observations

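The sorting test in this part was chosen after the results were seen; the splits and the test of earlier experiments were chosen before. Some members of the mesenchymal list, which camera did not call in either outgroup comparison and which went both ways, were high in the outgroup. FN1, which encodes fibronectin, was at 140.8 ± 15.7 in the outgroup against 18.7 ± 6.23 in pre and 17.5 ± 2.64 in post, and the collagen gene COL5A2 was at 101.7 ± 4.61 against 7.89 ± 1.49 and 6.86 ± 0.735. POSTN, which encodes periostin, was at 22.5 ± 7.11 against 0.875 ± 0.602 and 0.253 ± 0.223. FRZB, a secreted Wnt inhibitor gene, was at 42.1 ± 3.49 in post, 18.3 ± 4.1 in pre and 3.48 ± 0.982 in the outgroup. The FGF receptor gene FGFR2 was at 102 ± 7.64 in post, 75.3 ± 14.2 in pre and 10.8 ± 0.849 in the outgroup, while the ERK phosphatase gene DUSP6 was at 314 ± 48.6, 317 ± 49.3 and 35.5 ± 3.1.

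Hypoxia and glycolysis genes were higher and mitochondrial messenger RNAs lower in the outgroup than in pre, with medians of 0.69 and -0.62. Camera called both lists at the preset correlation alone (adjusted p = 0.189 and 0.43 with an estimated correlation). PDK1, which encodes a pyruvate dehydrogenase kinase, was at 61.0 ± 8.27 against 17.3 ± 5.1, and MT-ND1 at 1333 ± 203 against 2978 ± 402. The earlier experiments alone gave 0.87 and -0.61, which argues against a difference between earlier and later experiments. Sorting, which the outgroup did not pass through, cannot be told apart from the fate: the sorted groups differed from each other by medians of 0.18 and 0.02, but these pooled values hide a difference between experiments. The hypoxia median of post minus pre was 0.44 in the earlier experiments and -0.13 in the later ones (camera adjusted p = 0.00327 and 0.374, at the preset correlation). The mitochondrial one was -0.13 and 0.17 (camera adjusted p = 0.398 and 0.0333). Post replicate 2 had the highest mean log2 value over the hypoxia list, 5.92 against 5.56, 5.41 and 5.43 in post replicates 1, 3 and 4. Experiment 1 had 5.51 in pre and 5.56 in post, so the earlier hypoxia difference came largely from post replicate 2. In the earlier experiments the outgroup was still above post by a hypoxia median of 0.69 (camera adjusted p = 0.00394). There was no sorted outgroup or unsorted pre library. A metabolic difference of mesendoderm from ectoderm-directed cells was not tested apart from it.

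Other splits of the same libraries were counted, 35 for each comparison with the real one included. For genes in post against pre, 2 of 35 gave as many as the real 1127, so a chance split cannot be excluded by this count. The highest other split, with 1661, set the earlier experiments against the later ones. With the outgroup kept in the fit, the real comparison gave 88 genes within the earlier experiments and 758 within the later ones. With the replicate number as a block it gave 537 with only the pre and post libraries in the fit, against 453 without the block, and 1855 with the outgroup kept. Among the 8 splits that part all 4 pairs, the highest other gave 3 genes, and 11 lists, as many as the real one; the remaining splits leave some experiment whole on a side. For fate-specific genes 2 of 35 splits gave as many as 821, and the highest other, 1129, was again earlier against later. For lists in post against pre 8 of 35 gave 11 or more, with a highest other of 13, so chance cannot be excluded for the number of lists.

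For genes in outgroup against pre 1 of 35 splits, the real one, gave 5484, with a highest other of 3664. That other split set pre replicate 1 with the outgroup against the other pre libraries. For genes in outgroup against post 1 of 35 gave 7140, with a highest other of 5. The real split ranked first in both, but 1 of 35 is the smallest share that this count can give. The count alone therefore does not exclude chance. The outgroup also differed from the sorted groups in experiments, medium and sorting, which the splits cannot take apart from fate. For lists chance cannot be excluded: 5 of 35 splits gave 13 or more in outgroup against pre, with a highest other of 17, and 6 of 35 gave 13 or more in outgroup against post, with a highest other of 15.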
